A study of Mus musculus with 15 samples.

How the data were processed

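The 15 libraries were made from tumours of MDA-MB-231 cells with the Illumina TruSeq stranded RNA kit and sequenced as 50 bp single-end reads, per the labels' protocols. Per the submitters' processing notes, cutadapt, FastQC, STAR, HTSeq and DESeq2 were used and the genome build was hg19. The notes used here give no versions, and whether reads were counted by strand is not given in the sources used here. The labels give the organism as mouse, while the gene symbols and the build are human, so the values are reads counted on human genes, and reads of the mouse host that align to conserved human genes may be among them.

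The authors deposited raw counts per gene symbol, whole numbers for 25382 genes in 15 libraries, of which 4710 genes have no count in any library. The deposited table of normalized values holds log2 values: each equals log2 of the raw count divided by the library's median-of-ratios size factor plus 1, to within 5.15e-14 when recomputed here. The counts were the basis of every test, and the log2 values served the limma-trend alternatives. No column of either table lay outside the 15 samples. No human gene coordinates were used here.

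Libraries were grouped by the adhesion profile in the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood fit, all 15 libraries in a single fit with the group as the only term), which left 15190 genes with 99.98% of the counts. The test was two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 3 contrasts between the groups and a test for any difference among them were made. The biological coefficient of variation was 33.6%. CPM values are TMM-scaled, given as mean ± SD over libraries, and fold changes are given with standard errors and 95% confidence intervals, which cover the spread between libraries. edgeR's test gives no standard error, so it was derived as the absolute log2 fold change divided by the square root of the F statistic. The intervals use this value with the t distribution and are approximate. The reads carry no molecular identifiers as far as the labels say, so limits that come from a count of 0 cover counting error only, and such a limit was set at 3 counts.

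The design, the gene lists, the rule for named genes and the other settings to try were fixed before the data were examined. There were 34 lists with 978 entries, of which 977 were in the table, and 33 had at least 5 tested members. They cover adhesion, cytoskeleton, matrix, growth and stress pathways, metabolism, interferon and cytokines, and markers of 9 other cell types. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists within a comparison. Camera compares a list with the other genes, and fry tests whether the genes of a list move on balance in 1 direction. Mean log2 CPM of the lists for other cell types was compared with two-sided exact permutation tests over all relabelings, adjusted over 27 tests.

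The genes named in a comparison are the 10 with the largest and the 10 with the smallest fold change among those past the threshold at a mean of at least 1 CPM, or, where fewer than 5 pass, the 10 of smallest p at that mean, given as values. From each list called, up to 4 members past the threshold are named, or the 2 of highest mean CPM where none passes, and not every gene this rule picks is used here. ITGB1, PTK2, VIM, CDH1, MKI67 and CD44 are always given. Pseudogenes, antisense genes and genes without a proper symbol were counted but not named, and the pattern that recognises pseudogenes was corrected once after the first output had been seen because it had removed PSIP1, a protein-coding gene. Ribosomal protein, actin, tubulin, myosin and HLA genes have near-identical copies, so their single-gene values are uncertain.

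Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter or a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with and without sample weights, limma-trend on the authors' deposited log2 values with a pseudocount of 1 or 8, the title number as a block, a fit of the 2 groups alone, and each library left out. Fits without title number 6, without title number 6 and strongly adherent library 5, and DESeq2 with the block were added after seeing the data. So was a contrast of each title number with the rest, adjusted for adhesion group, in which all 6 numbers were treated alike. No pair of libraries of the same adhesion group agreed within sampling noise, so none is the same library sequenced again. Pairs across groups were not compared in this way, and libraries of the same animal would also differ by more than sampling noise.

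The edgeR contrasts between groups and camera were checked on simulated counts drawn from the real means and library sizes. Fry, the exact permutation tests and the test for any difference among the groups were not scored in this way. In the simulated counts 200 genes were changed by 2-fold or 4-fold and the 34 focal adhesion genes were raised by 2-fold. Counting both, between weakly and strongly adherent tumours the fit called 188 genes, 6 of them unchanged, between weakly adherent and unsorted 203 with 9 unchanged, and between strongly adherent and unsorted 194 with 8 unchanged. The shift of the focal adhesion list was called by camera with the preset and with the estimated correlation, and no other list was called. The simulated genes varied independently, while the estimated correlation in the real data was 0.728 for the mitochondrial genome and 0.824 for the ribosomal proteins. The check therefore cannot show how often camera at the preset correlation calls unchanged lists of correlated genes.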

Results

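The libraries came from primary tumours of MDA-MB-231 cells, a human triple-negative breast cancer line, here carrying GFP and luciferase and grown in mice of a strain labelled Nod/Skid. The cells had been sorted by how firmly they hold on under fluid shear. Weakly adherent cells were taken at 10 dyn per square centimetre, strongly adherent cells at 50 dyn per square centimetre, and unsorted cells saw no shear. The tumours were removed and dissociated, and bulk mRNA of the cells was sequenced. There were 4 libraries of strongly adherent, 5 of unsorted and 6 of weakly adherent origin. Each library is named here by its adhesion group and by the number in its title (4, 5, 6, 7-8, 9 or 10). The titles put the word Group before that number, as in Group 4 Strongly Adherent, so they may name sets of libraries. The labels do not say what the number or such a set stands for. Total counts per library ran from 30372619 to 45434799, and 16760 to 17974 genes had at least 1 count. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may in part be technical.

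E-cadherin, the main adhesion protein of epithelial cell junctions, separated the 3 libraries titled number 6 from the other 12. Its gene CDH1 stood at 0.267, 0.407 and 5.56 CPM (counts scaled to the size of the library) in strongly adherent, unsorted and weakly adherent library 6, and between 53.1 and 549 CPM in the other 12. VIM, which encodes the mesenchymal filament protein vimentin, stood at 6489 to 7399 CPM in the libraries titled number 6 and at 1143 to 4478 CPM in the others. Genes of striated muscle set strongly adherent library 5 apart as well. ACTA1, skeletal muscle actin, was counted at 864 CPM there, at 133, 350 and 53.4 CPM in strongly adherent, unsorted and weakly adherent library 6, and at no more than 3.24 CPM in the other 11. The first principal component held 51.8% of the variance between libraries, and 90.1% of its spread lay between title numbers against 1.47% between adhesion groups. The second component held 10.7%, of which 31.0% lay between title numbers and 20.9% between adhesion groups, with strongly adherent library 5 at 73.0 and the next library, unsorted library 6, at 26.2. There are more title numbers than groups, so chance alone puts more spread between title numbers. The shares of the second component therefore do not rank these labels.

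**Figure D1:**
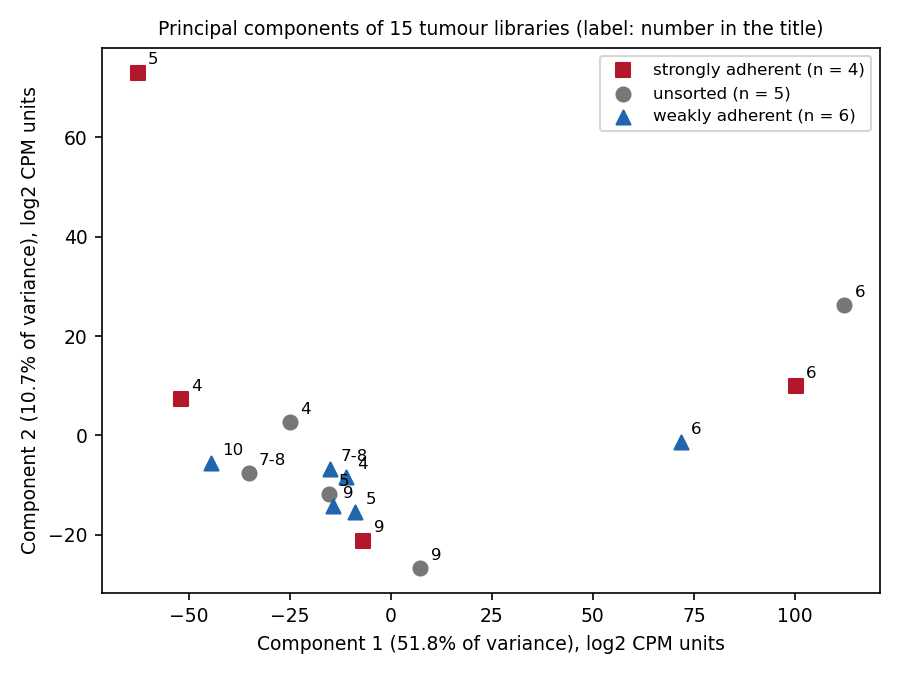
Principal components 1 and 2 of log2 CPM for the 15 libraries, coloured by adhesion group and labelled with the number in the title. The 3 libraries titled number 6 lie between 71.7 and 112 on the first component, and the other 12 lie between -62.7 and 7.22.

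**Figure D2:**
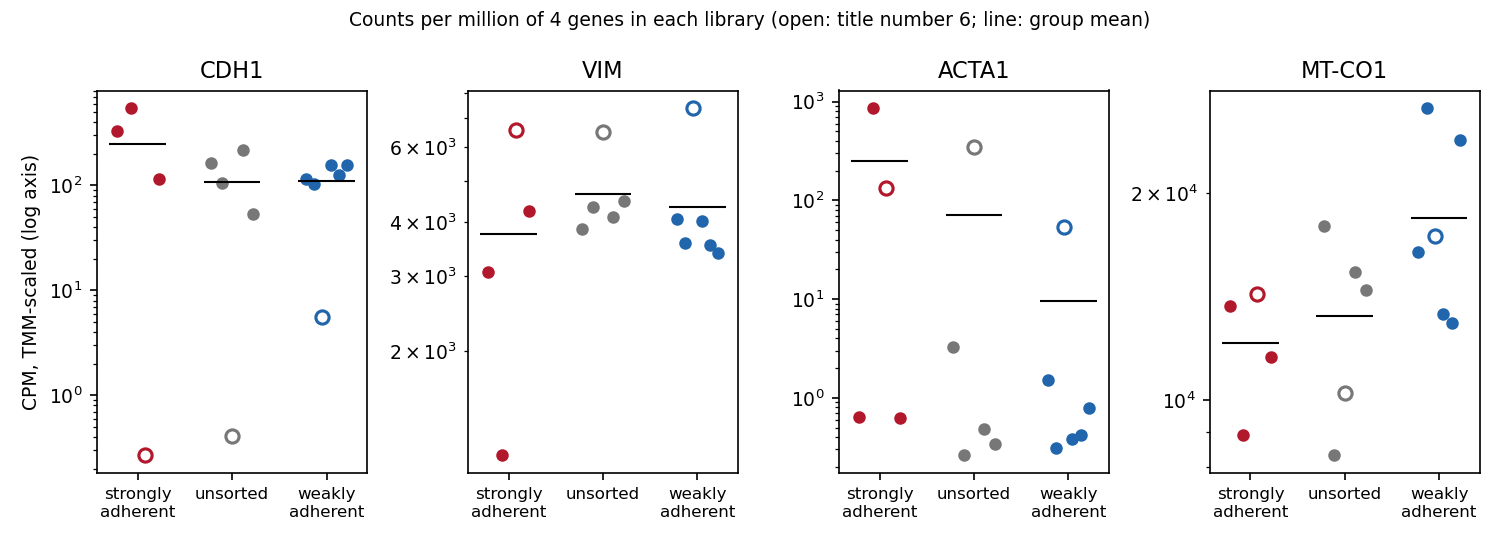
CPM of CDH1, VIM, ACTA1 and MT-CO1 in each library on log axes, by adhesion group, with open symbols for title number 6 and a line at the group mean. CDH1 is at most 5.56 CPM in the open symbols and at least 53.1 CPM in the filled ones.

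The comparison of weakly with strongly adherent origin asked whether the sorted adhesion class of the cells left a mark on the mRNA of their tumours. As a set, the 13 protein genes of the mitochondrial genome rose in tumours of weakly adherent cells, with 13 positive fold changes and a median log2 fold change of 0.64. MT-CO1, a subunit of cytochrome c oxidase, stood at 18408 ± 5602 CPM (SD, n = 6) against 12104 ± 2436 CPM (SD, n = 4). The cytosolic ribosomal proteins rose as a set (57 of 57 positive, median 0.20), as did nuclear genes of oxidative phosphorylation (43 of 45, median 0.14), cholesterol and lipid synthesis (24 of 32, median 0.12), cell cycle genes (41 of 50, median 0.09) and fibroblast markers (13 of 19, median 0.19). Muscle markers fell as a set (16 of 18 negative, median -4.28), and so did immediate early and dissociation genes (28 of 38, median -0.15) and genes of the unfolded protein and amino acid stress response (19 of 28, median -0.13). These 9 of 33 lists passed limma's camera test at a preset correlation, with adjusted p from 1.73e-11 for the mitochondrial genome to 0.0495 for the stress response and the fibroblast markers. With an estimated correlation none of the 9 passed, each at adjusted p = 0.787 with an estimated correlation, and fry called 0 lists. That correlation was 0.728 for the mitochondrial genome and 0.824 for the ribosomal proteins. Members of such a list move together, so the number of fold changes of the same sign adds little evidence.

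No member of these lists passed by itself, and the most abundant members are given as values. RPS18 stood at 2711 ± 1111 CPM in weakly (n = 6) and 2158 ± 750 CPM in strongly adherent tumours (n = 4), a log2 fold change of 0.33 ± 0.28 (SE), and RPLP0 had 0.17 ± 0.15. ATP5B and ATP5A1, of the mitochondrial ATP synthase, had 0.02 ± 0.11 and 0.18 ± 0.13. ACLY, which supplies acetyl-CoA for lipid synthesis, had 0.18 ± 0.11. Cyclin D1 (CCND1) and topoisomerase TOP2A each had a log2 fold change of 0.01. The chaperone genes CALR and HSP90B1 had positive values, 0.11 and 0.06, within a stress list that fell, and HSPA8 and HSP90AA1 had -0.18 and 0.03. COL1A1 had -0.27 ± 0.50 and COL6A3 0.42 ± 0.47 among the fibroblast markers. The muscle genes ACTA1 and CKM had -4.73 ± 2.41 and -5.30 ± 2.56, with CKM at 467 CPM in strongly adherent library 5 and 61.9 CPM in strongly adherent library 6.

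No single gene passed between weakly and strongly adherent tumours in fits with the group as the single term. edgeR's quasi-likelihood test called 0 of 15190 genes, with 366 at an unadjusted p under 0.05 where chance gives 759.5, and DESeq2, limma voom and limma-trend with the same single term for the group also called 0. In edgeR with the title number as a block, which called 0 too, 1030 genes were under that unadjusted p. The number was 815 without title number 6 and 134 without title number 6 and strongly adherent library 5. A count under chance thus depends on the libraries and terms fitted, and does not show that adhesion has no effect. DESeq2 with the title number as a block, added after seeing the data, called 36, as given below. The 10 genes with the smallest p among those with a proper symbol and a mean of at least 1 CPM are given as values, here and below. RAB3D, a GTPase of regulated secretion, stood at 19.6 ± 1.85 CPM in weakly (SD, n = 6) and 31.0 ± 6.41 CPM in strongly adherent tumours (SD, n = 4), a log2 fold change of -0.66 ± 0.13 (SE). CCNA1, a cyclin, had 1.07 ± 0.24, the cell adhesion molecule gene NRCAM -1.10 ± 0.27, and CDKN2C, an inhibitor of cyclin-dependent kinases, 0.51 ± 0.13. PSIP1, NDC80, PDLIM3 and MRAS had values of 0.39, 0.36, 0.63 and 0.63, and TBC1D8 and the cationic amino acid transporter gene SLC7A2 had -0.72 and -0.87. Of the 9 list calls, those of the mitochondrial genome, cholesterol synthesis and muscle stood when any 1 library was left out. The cell cycle call was lost without strongly adherent library 6 (adjusted p = 0.955), the ribosomal call without strongly adherent library 5 (0.135) and the oxidative phosphorylation call without weakly adherent library 6 (0.0836), all by camera. The stress response lost its call without strongly adherent library 6 (0.916) and weakly adherent libraries 5 (0.184), 7-8 (0.0937), 9 (0.138) and 10 (0.156). The immediate early genes lost theirs without strongly adherent libraries 4 (0.146) and 6 (0.817) and weakly adherent libraries 5 (0.0795), 9 (0.327) and 10 (0.330). The fibroblast markers lost theirs without strongly adherent library 6 (0.955) and weakly adherent libraries 4 (0.285), 5 (0.0795), 9 (0.0743) and 10 (0.314). Without title number 6, a setting chosen after seeing the data, 4 of the 9 remained past: the mitochondrial genome, nuclear oxidative phosphorylation, ribosomal proteins and muscle. Without title number 6 and strongly adherent library 5 only 2 remained, the mitochondrial genome and cell cycle, with adjusted p of 0.547 for cholesterol synthesis and 0.0723 for muscle. Without strongly adherent library 5 alone the number of lists past was 14.

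Weakly adherent against unsorted tumours asked whether the weakly adherent fraction differs from the whole population it was taken from. The mitochondrial genome genes rose here as well as a set (13 of 13 positive, median log2 fold change 0.46), and MT-ND4, a subunit of complex I, stood at 12775 ± 3386 CPM (SD, n = 6) against 9262 ± 3079 CPM (SD, n = 5). Both comparisons use the same weakly adherent libraries, so this repeat is no independent evidence. Interferon response genes rose as a set (42 of 44 positive, median 0.16), though its most abundant members differed little, with 0.10 ± 0.56 (SE) for IFI27 and 0.07 ± 0.20 for IFITM3. Cholesterol and lipid synthesis (24 of 32 negative, median -0.06) and nuclear genes of oxidative phosphorylation (30 of 45 negative, median -0.02) fell as sets, with log2 fold changes of -0.03 for ACLY, -0.08 for ATP5B and -0.11 for ATP5A1. Camera's adjusted p was 1.58e-11, 0.00786, 0.0141 and 0.0212 for these 4 lists, each at adjusted p = 0.997 with an estimated correlation, and fry called 0. The share of all counts that fell on the mitochondrial genome was 10.7%, 10.2% and 9.93% in weakly adherent libraries 5, 6 and 10. It was 7.04%, 6.57% and 5.78% in weakly adherent libraries 4, 7-8 and 9, below the 7.65%, 7.55% and 6.30% of the unsorted libraries of the same numbers. The shares ran from 3.65% to 7.65% in the 5 unsorted and from 3.71% to 7.77% in the 4 strongly adherent libraries.

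No gene passed between weakly adherent and unsorted tumours by edgeR's quasi-likelihood test (0 of 15190, with 81 at an unadjusted p under 0.05). With the same single term for the group, 0 passed by DESeq2, limma voom or limma-trend. DESeq2 with the title number as a block did call genes, as given below. DAPK1, a death-associated kinase, had the largest fold among the 10 genes of smallest p with a mean of at least 1 CPM, at 2.33 ± 1.06 CPM (SD, n = 6) against 0.982 ± 0.330 CPM (SD, n = 5), a log2 fold change of 1.24 ± 0.45 (SE). ENPP4, ZNF155, TRIM59, PRTG, DZANK1, NHLRC1 and ZFP69B had log2 fold changes between 0.35 and 0.51, and UBL4A and ACTRT3 had -0.20 and -0.57. The interferon call ended without unsorted library 6, where the set's direction turned (camera adjusted p = 0.391), and also without weakly adherent library 5 (0.0599), without weakly adherent library 10 (0.399) or without the 3 libraries titled number 6. Interferon genes were low in these 3 (mean log2 CPM of 3.99, 3.97 and 4.84 against 5.56 to 6.84 in the other 12). The cholesterol call ended without weakly adherent libraries 5 (0.528) and 10 (0.666) and unsorted library 6 (0.482). The oxidative phosphorylation call ended without unsorted libraries 4 (0.159), 5 (0.0635) and 6 (0.187) and weakly adherent libraries 4 (0.251), 5 (0.239) and 9 (0.662), while the mitochondrial genome kept its call without any 1 library. The number of lists past ranged from 1, without weakly adherent library 5, to 9, without weakly adherent library 6.

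Strongly adherent against unsorted tumours asked the same of the strongly adherent fraction. Nuclear genes of oxidative phosphorylation fell as a set in tumours of strongly adherent cells (44 of 45 negative, median log2 fold change -0.16), as did cytosolic ribosomal proteins (56 of 57, median -0.14), cholesterol and lipid synthesis (27 of 32, median -0.18) and cell cycle genes (40 of 50, median -0.11). Of the cytoskeleton, the actomyosin contractility list (18 of 32 negative, median -0.13) and the microtubule list (25 of 40, median -0.07) fell. The tubulin genes TUBB and TUBA1B had -0.32 ± 0.14 (SE) and -0.34 ± 0.16, with TUBB at 2556 ± 345 CPM (SD, n = 4) against 3190 ± 373 CPM (SD, n = 5), while the actin genes ACTB and ACTG1 had -0.12 and 0.03. Muscle markers rose as a set (17 of 18 positive, median 1.81), with 1.81 ± 2.32 for ACTA1 and 2.63 ± 2.45 for CKM. These 7 lists passed camera at adjusted p from 8.95e-08 for oxidative phosphorylation to 0.0374 for the 2 cytoskeleton lists. None passed with an estimated correlation (adjusted p = 0.850 with an estimated correlation for the ribosomal proteins, 0.762 for the other 6) or by fry. ATP5A1 had -0.28 ± 0.14, ATP5B -0.10 ± 0.11, RPLP0 -0.19 ± 0.16, RPS18 -0.10 ± 0.29, and ACLY -0.21 ± 0.12, and the cell cycle genes CCND1 and TOP2A had -0.09 and 0.11.

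No gene passed between strongly adherent and unsorted tumours by edgeR's quasi-likelihood test (0 of 15190, smallest adjusted p = 0.9748, with 572 at an unadjusted p under 0.05). With the same single term for the group, 0 passed by DESeq2, limma voom or limma-trend. DESeq2 with the title number as a block did call genes, PDLIM3 and SLC7A2 among them, as given below. The values that follow are edgeR's. PDLIM3, a muscle and actin-associated LIM protein gene, had the smallest p, with 4.93 ± 1.17 CPM (SD, n = 4) against 8.49 ± 1.77 CPM (SD, n = 5) and a log2 fold change of -0.79 ± 0.18 (SE). TBC1D8, RAB3D and SLC7A2, also among the smallest p against weakly adherent tumours, had 0.87, 0.54 and 1.02 here, and PSIP1 had -0.38. These comparisons share the strongly adherent libraries, so such repeats are no independent evidence. AHR, the aryl hydrocarbon receptor gene, had 0.64 ± 0.18, GOLGA3 0.34 ± 0.09 and PRTG 0.69 ± 0.19, while the circadian transcription factor gene DBP had -0.73 ± 0.20 and UBTD1 -0.57 ± 0.14. The muscle call was lost without strongly adherent library 5 (camera adjusted p = 0.439) or library 6 (0.0939), the ribosomal call without strongly adherent library 5 (0.439), the cell cycle call without strongly adherent library 6 (0.468). The actomyosin call was lost without unsorted libraries 4 (0.187), 6 (0.0657) and 7-8 (0.0766) and strongly adherent library 6 (0.660), and the microtubule call without unsorted libraries 4 (0.0853) and 6 (0.240) and strongly adherent library 6 (0.270). Without title number 6 the calls for oxidative phosphorylation, ribosomal proteins, cholesterol synthesis and muscle remained.

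**Figure D3:**
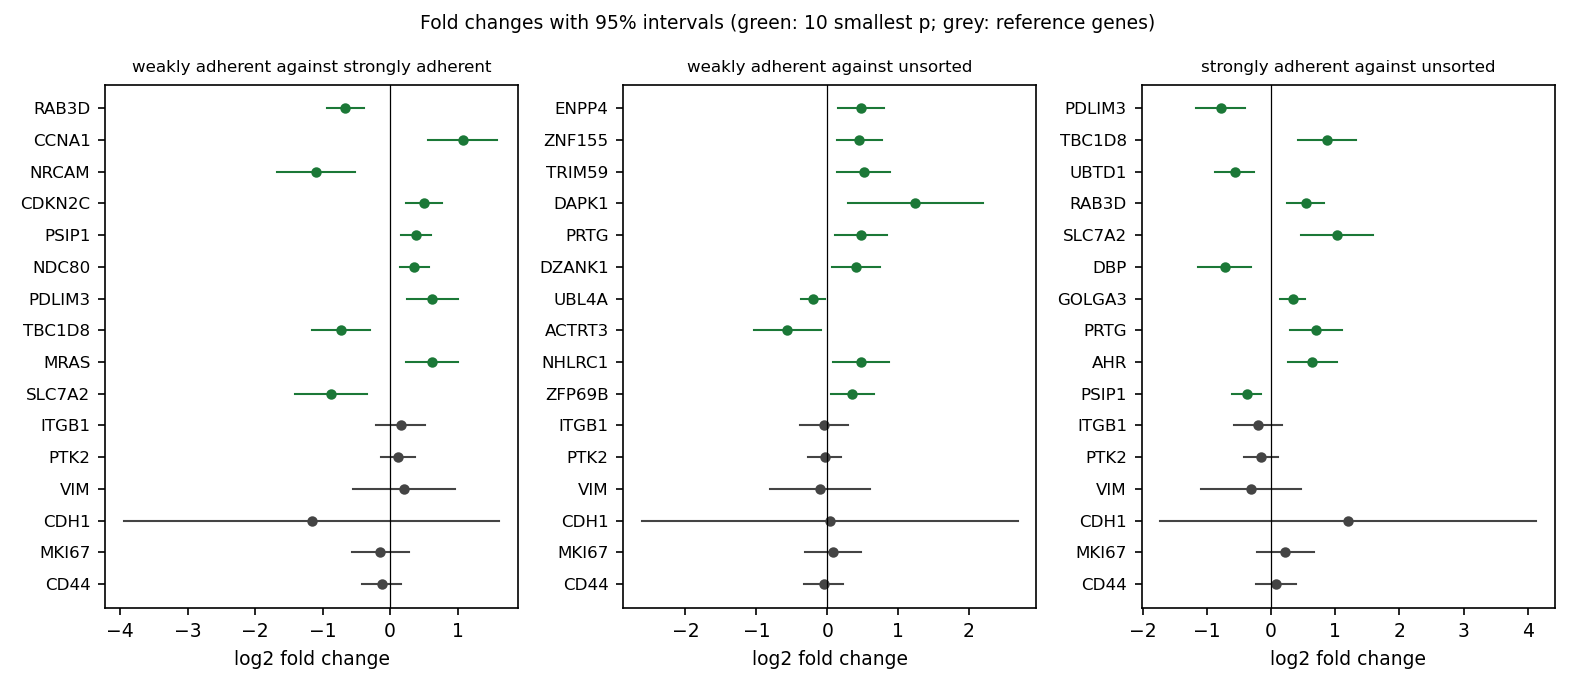
Log2 fold changes with 95% confidence intervals for the 10 genes of smallest p with a mean of at least 1 CPM in each comparison (green) and 6 reference genes (grey). None of these genes passed the adjusted threshold, and the CDH1 intervals are the widest of the reference genes, reaching from -3.95 to 1.62 between weakly and strongly adherent tumours.

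**Figure D4:**
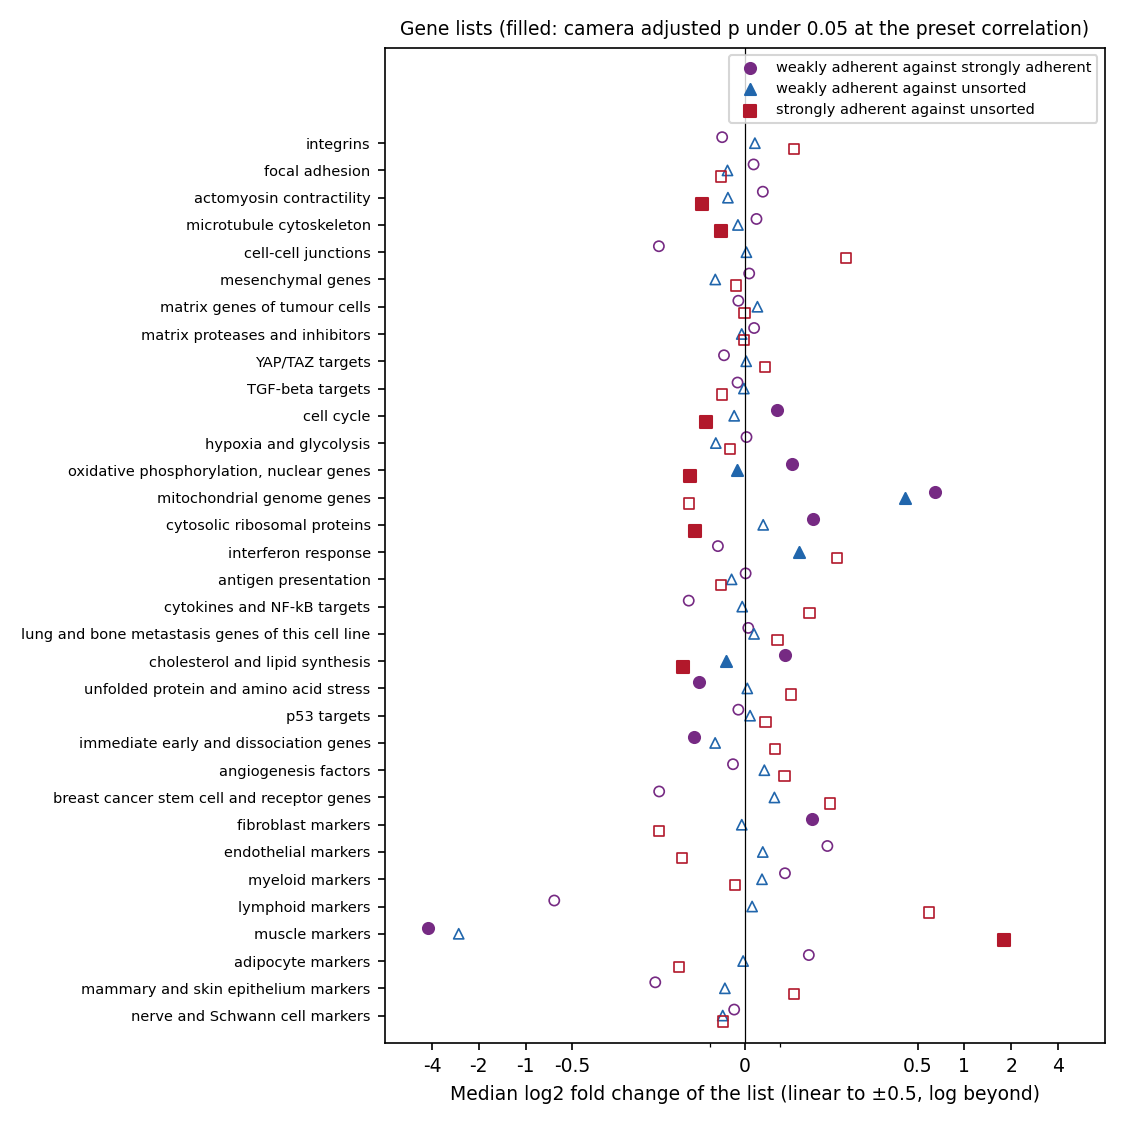
Median log2 fold change of the 33 tested lists in the 3 comparisons, on an axis that is linear to 0.5 in either direction and logarithmic beyond, with filled symbols for lists past camera at the preset correlation. The mitochondrial genome genes lie at 0.64 and 0.46 for weakly adherent tumours against strongly adherent and unsorted ones.

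No gene of adhesion itself passed in any comparison. ITGB1, the integrin subunit shared by most matrix receptors, stood at 1133 ± 75.7 CPM in strongly adherent (SD, n = 4), 1306 ± 258 in unsorted (n = 5) and 1264 ± 280 in weakly adherent tumours (n = 6), and the log2 fold change of weakly against strongly adherent was 0.16 with a 95% interval from -0.21 to 0.52. PTK2, which encodes focal adhesion kinase, had 0.12 (-0.13 to 0.37), the hyaluronan receptor gene CD44 -0.13 (-0.42 to 0.17), the proliferation marker MKI67 -0.14 (-0.57 to 0.28) and VIM 0.21 (-0.55 to 0.96). CDH1 had -1.16 with an interval from -3.95 to 1.62. The 19 tested integrins had camera adjusted p of 0.400, 0.435 and 0.897 for weakly against strongly adherent, weakly against unsorted and strongly against unsorted. In the same order, the 34 focal adhesion genes had 0.331, 0.135 and 0.0527, the 30 cell-cell junction genes 0.623, 0.435 and 0.328, the 23 YAP/TAZ targets 0.331, 0.990 and 0.382, and the 23 mesenchymal genes 0.849, 0.204 and 0.328. None of the listed genes passed in any of the 3 comparisons, adjusted over all genes or adjusted over the list alone. The median, the mean and camera's direction differed in sign for 11, 10 and 6 of the 33 lists in the 3 comparisons, the integrins among them in the first and the third, and for none of the lists that were called.

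The test for any difference among the 3 groups, with the group as the single term, also called no gene: 0 of 15190 by edgeR, with 258 at an unadjusted p under 0.05, and 0 by DESeq2, limma voom and limma-trend. DESeq2 with the title number as a block did call genes here too, as given below. The width of the intervals says what could have been seen. The median half-width of the 95% interval was 0.36, 0.34 and 0.37 on the log2 scale for weakly against strongly adherent, weakly against unsorted and strongly against unsorted. In 85.8%, 89.3% and 84.2% of the 13138 genes with a mean of at least 1 CPM the whole interval lay within a 2-fold change either way. In simulated counts with these group sizes, 63%, 72% and 66% of genes changed by 2-fold and 93%, 94% and 91% of genes changed by 4-fold were recovered in the 3 comparisons. The simulated genes varied independently, while in the real libraries many genes differed together between title numbers. These rates therefore hold for the simulated counts and may be too high for the real ones.

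Markers of other cell types were compared because the tumours grew in mice and reads of host cells can be counted on conserved human genes. Fibroblast markers had a mean log2 CPM of 3.80 ± 0.45 in weakly adherent (SD, n = 6), 3.59 ± 0.59 in strongly adherent (n = 4) and 3.80 ± 0.44 in unsorted tumours (n = 5). Endothelial markers had 1.71, 1.49 and 1.71 in the same order, myeloid markers 2.41, 2.13 and 2.33, lymphoid markers 0.51, 0.58 and 0.24, and adipocyte markers 2.19, 1.99 and 2.17. Mammary and skin epithelium markers had 3.99, 4.18 and 3.82, nerve and Schwann cell markers 2.73, 2.73 and 3.03, and the 2 tested erythroid markers -1.34, -0.91 and -1.34. Muscle markers had -1.10 ± 1.65, 1.499 ± 3.64 and -0.42 ± 2.70. Exact permutation tests over these 9 lists and 3 comparisons gave 0 of 27 past the threshold, 0 at an unadjusted p under 0.05, and a smallest adjusted p of 0.904, where the smallest unadjusted p the group sizes allow is 0.00476, 0.00216 and 0.00794 for the 3 comparisons. Over 27 tests even that p does not pass for a single list, so a difference in only 1 list could not have been called.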

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

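The gap test on single libraries follows a fixed rule, and the test of muscle markers was chosen after the result was seen. In each adhesion group, a gap test asked whether the highest or lowest library lay farther from its nearest neighbour than Dixon's 95% limit, and 19 of 195 groups of values exceeded it, where chance gives about 5%. Of the 19, 15 were in libraries titled number 6 and 1 in strongly adherent library 5.

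Among single genes, unsorted library 6 was highest for ITGB1 (1755 CPM, next 1247), PTK2 (288 CPM, next 219), VIM (6489 CPM, next 4478) and ZFP69B (6.84 CPM, next 5.54). Weakly adherent library 6 was highest for VIM (7399 CPM, next 4067) and lowest for CDH1 (5.56 CPM, next 103). Strongly adherent library 5 was highest for GOLGA3 (92.4 CPM, next 79.5).

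Among list means in log2 CPM, strongly adherent library 6 was lowest for the microtubule cytoskeleton (5.94, next 6.21) and for matrix genes of tumour cells (6.55, next 7.12). Weakly adherent library 6 was lowest for cell-cell junctions (4.70, next 5.77), for the interferon response (4.84, next 6.07) and for mammary and skin epithelium markers (3.26, next 4.00). Unsorted library 6 was lowest for the interferon response (3.97, next 5.83) and for breast cancer stem cell and receptor genes (2.79, next 3.85). Unsorted library 5 was lowest for YAP/TAZ targets (6.40, next 6.62), and weakly adherent library 7-8 for myeloid markers (1.97, next 2.44). Weakly adherent library 4 had the largest total count, 45.4 M (45434799 counts), with the next at 37.1 M.

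Muscle markers stood out in unsorted library 6 (mean log2 CPM 4.32, next -0.78) and weakly adherent library 6 (2.22, next -1.26), and strongly adherent libraries 5 and 6 were at 5.76 and 3.29 against -1.47 and -1.58 for the rest of their group. Of 18 tested muscle markers, at least 15 reached 1 CPM in these 4 libraries and at most 5 in each of the other 11, libraries picked by these same values, so no groups were tested. Muscle of the host beside the tumour may be the source, since dissociation carries along whatever tissue is removed with a tumour and no step that would remove host cells is named in the labels. ACTA1 and CKM reached 864 and 467 CPM in strongly adherent library 5. Host muscle cannot be told apart from muscle genes switched on in the tumour cells, because counts per gene do not show whether a read was mouse or human.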

How the results depend on the processing

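The fits without title number 6, without title number 6 and strongly adherent library 5, and DESeq2 with a replicate block were chosen after the result was seen. The count of 0 genes held in all 3 comparisons and in the test for any difference under every planned scaling, filter, tool and left-out library, with 232 to 759, 56 to 179, 312 to 1122 and 156 to 471 genes at an unadjusted p under 0.05 when 1 library was left out. It also held without title number 6, with or without strongly adherent library 5.

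Same-numbered libraries did not pair by the rule used: of 13 same-number pairs 11 correlated above 0.1 after the group means were removed, and the lowest was at 0.016. The median was 0.258 over the same-number pairs and -0.026 over the other pairs, so a paired design is not excluded. If the libraries were paired, the fits with the adhesion group as the single term left that pairing out. As a hint from the data, 9 of 14 libraries with a partner correlated best with one of their own number, among them all 3 of number 6. With the number as a replicate block, edgeR still called 0 genes, but DESeq2 called 36 (11 higher, 25 lower) between weakly and strongly adherent tumours, 10 (5 and 5) between weakly adherent and unsorted, 23 (20 and 3) between strongly adherent and unsorted, and 32 for any difference. RAB3D and SLC7A2 passed there in the first comparison and PDLIM3 and SLC7A2 in the third, and the cause of the gap between the tools was not tested. With the block 9, 4 and 9 lists passed, but the stress, immediate early and fibroblast calls were lost in the first comparison, cholesterol in the second and actomyosin in the third.

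List calls depended on the setting most. The counts of lists past, 9, 4 and 7, became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry, and the second became 7 when only the libraries of its 2 groups were fitted. Leaving out 1 library gave 6 to 14, 1 to 9 and 6 to 12. Between weakly and strongly adherent tumours the highest count came without strongly adherent library 5. Between strongly adherent and unsorted it was 12 without strongly adherent library 9 and 11 without unsorted library 5. Between weakly adherent and unsorted it was 9 without weakly adherent library 6, 8 without weakly adherent library 4, 7 without unsorted library 5, 7-8 or 9 or weakly adherent library 7-8, 2 without unsorted library 6 or weakly adherent library 10 and 1 without weakly adherent library 5. Of 357 values for the 20 list calls 243 stayed past, 108 lost the call and 6 turned direction.

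Between weakly and strongly adherent tumours the stress response turned without strongly adherent library 6 (adjusted p = 0.916) and without title number 6 and strongly adherent library 5 (0.925), the immediate early genes turned without strongly adherent library 6 (0.817), and cell cycle turned without title number 6 (0.900). The stress list had its smallest adjusted p, 0.000744, without strongly adherent library 9. For immediate early and dissociation genes adjusted p, weakly adherent against strongly adherent, was 1.03e-05 without strongly adherent library 5. All 3 of the stress, immediate early and fibroblast lists also lost their calls without weakly adherent library 5, 9 or 10, and each without further libraries. Between weakly adherent and unsorted, interferon turned without unsorted library 6 (0.391) and reached 0.399 without weakly adherent library 10 and 1.43e-05 without weakly adherent library 6. Oxidative phosphorylation reached 5.07e-08 without the same library and turned without weakly adherent library 9 (0.662), and lost its call without library 4 or 5 of either group or unsorted library 6. Cholesterol synthesis lost its call without weakly adherent library 5 or 10 or unsorted 6. Between strongly adherent and unsorted, both cytoskeleton lists lost theirs without unsorted library 4 or 6 or strongly adherent library 6, and actomyosin also without unsorted library 7-8. For title number 6 against the other numbers, 4018 genes became 1642 without strongly adherent library 6 and 4543 without strongly adherent library 9. All 6 turns leave out libraries, and no further cause was tested. Of 2101 values for 88 named-gene results 2078 stayed as they were, 4 passed the threshold and 19 moved, and of 3042 values for 139 results on title number 6, 2867 stayed and 175 lost the call.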

Other observations

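The contrast of each title number with the rest was chosen after the principal components had been seen, as were its splits of the libraries and the tests of mouse symbols, MTAP and CDH1, while the splits for the adhesion comparisons were planned. The 3 libraries titled number 6 differed from the other 12 at 4018 genes (edgeR's quasi-likelihood test, adjusted for adhesion group), 1585 higher and 2433 lower, of which 782 were lower by at least 4-fold and 45 higher by at least 4-fold. The same contrast called 1 gene for number 9 and 0 for numbers 4, 5, 7-8 and 10, but number 10 is 1 library and 7-8 is 2, and the libraries titled number 6 add spread to each of these, so the zeros are weak evidence. Of 30 genes of cell-cell junctions 22 fell in number 6 and none rose, a list past camera at the preset correlation (adjusted p = 4.37e-11) but not with an estimated correlation (adjusted p = 0.590): TJP3 stood at 0.172 ± 0.120 CPM (SD, n = 3) against 4.98 ± 2.56 (SD, n = 12), CGN at 1.14 ± 1.07 against 35.0 ± 19.4, and CDH1 at 2.08 ± 3.02 against 183 ± 135. Of 44 interferon response genes 39 fell and 1 rose, with an adjusted p of 1.31e-18 at the preset and 0.590 with an estimated correlation: IFI44L stood at 5.05 ± 1.51 against 80.0 ± 27.2 CPM and RSAD2, an antiviral enzyme, at 0.501 ± 0.544 against 24.6 ± 9.54. Of 35 matrix genes 14 were lower and 4 higher, with the laminin gene LAMA3 at 51.8 ± 18.4 against 502 ± 209, and of 33 matrix proteases and inhibitors 9 were lower and 2 higher, with the collagenase gene MMP13 at 1.27 ± 1.27 against 114 ± 92.8. Of 19 fibroblast markers 11 were lower and 1 higher (median log2 fold change -1.31), of 15 mammary and skin epithelium markers 9 were lower and 1 higher (-1.10), and of 13 myeloid markers 6 were lower and 3 higher (-0.82). Of 15 endothelial markers 3 were lower and 1 higher (0.38), the higher being CDH5, the cadherin of blood vessels, at 7.93 ± 2.33 against 1.57 ± 1.42 CPM. The keratin genes KRT8 and KRT18 stood at 630 ± 82.4 and 306 ± 42.2 against 1476 ± 429 and 655 ± 176.

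Of 40 hypoxia and glycolysis genes 13 were higher in number 6 and 1 lower: CA9, a carbonic anhydrase induced by low oxygen, stood at 29.3 ± 7.21 CPM against 6.90 ± 3.40, LDHA at 3023 ± 64.2 against 1737 ± 410, and BNIP3 at 342 ± 33.5 against 169 ± 45.3. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 1279 ± 69.4 against 802 ± 105, and VIM at 6816 ± 506 against 3656 ± 895. The 10 genes with the largest rise were all of striated muscle, such as MYH7 at 19.8 ± 19.9 against 2.503 ± 8.66, and strongly adherent library 5 held most of the counts behind the second value. LRRC31, PKHD1, APCDD1 and TMEM125 had no count in the 3 libraries. They were at least 69.5-, 59.8-, 59.6- and 49.2-fold lower than the mean of the other 12, against a floor of 3 counts over the 3 libraries. These bounds do not hold for each library: APCDD1 stood at 1.64 ± 1.99 CPM in the other 12 and at 0.0282 CPM in weakly adherent library 5, near the floor of 0.0275 CPM. Camera called 17 of 33 lists and fry 17, but not the same ones. Of camera's lists, fry's adjusted p was 0.0538 for hypoxia and glycolysis, 0.0565 for immediate early genes, 0.0649 for nuclear oxidative phosphorylation, 0.111 for ribosomal proteins, and 0.245 for both the mitochondrial genome and cholesterol synthesis. None passed camera with an estimated correlation (smallest adjusted p = 0.590 with an estimated correlation). The median, mean and direction differed in sign for 7 lists, none of them called.

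Of 100 splits of the 15 libraries into 3 and 12, 1 of 100, the real one, gave 4018 genes or more, and the highest other gave 1099 and held 2 of the 3 libraries. Among 42 splits with 0 of the 3 libraries the highest gave 324 genes, and among 46 with 1 of them it gave 2, with a median of 0 in both. A large count thus did not always need a library titled number 6. Number 6 was picked because it stood apart, so these splits say how large the difference is and are no independent evidence for it. For lists, 2 of 100 splits, the real one among them, reached the 17 that camera called, and the other splits had a median of 9. Across 7 alternatives in scaling, filter, covariate and tool the count of genes lay between 3734 and 4780. With 1 library left out it lay between 1642 and 4543, lowest without strongly adherent library 6 (403 higher and 1239 lower). In no setting did any of the 4018 genes turn direction. In simulated counts, again drawn independently for each library, the contrast recovered 72% of genes changed by 2-fold and 95% of those changed by 4-fold.

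The genes lower in number 6 may mark cells that were present in the other 12 libraries and missing from these 3, or a shift in the state of the same cells, and fewer host cells stay open as part of it, since 11 of 19 fibroblast markers were lower, while myeloid and endothelial markers went both ways. Mouse reads counted on human genes are argued against as the whole cause: among genes at 1 CPM, 46 of 505 lower by 4-fold had no mouse gene of the same symbol (9.11%) against 1483 of 12633 others (11.7%), an odds ratio of 0.754 (95% interval 0.541 to 1.03, Fisher's exact p = 0.0765), where mouse reads alone should leave almost none. The share was 13.0% over all lower genes and 7.92% over those lower by 16-fold, all 3 shares were seen before the bound of 0.5 was set, and some genes without a mouse symbol are differently named orthologs. Human cells that express MTAP stay open: MTAP reached at most 0.618 CPM in the other 12 libraries, under a bound of 1 CPM that was set after the values were seen, but it was higher there (0.307 ± 0.190) than in number 6 (0.0526 ± 0.0664), and the level such cells would bring is not known. CDKN2A, also looked at, had 0 CPM in all 15 libraries, so it does not set number 6 apart from the other 12. No biological explanation was tested. A further human population in the other 12 cannot be told apart from a changed state, because counts per gene hold no genotype. CDH1 was at least 53.1 CPM in each of the 12. The genes that follow were chosen after their values were seen, and no list of lung genes was tested. NKX2-1, a lung and thyroid transcription factor gene, stood at 24.5 ± 15.7 CPM in the 12 against 0.142 ± 0.224 in number 6. SFTPB, a surfactant protein gene, stood at 70.4 ± 62.7 against 0.318 ± 0.103. SLC34A2 stood at 22.0 ± 19.6 against 0.0664 ± 0.0620, and SFTA2 at 4.35 ± 3.09 against 0.0102 ± 0.0177. Whether number 6 or the other 12 lie closer to the cells before grafting cannot be told, because every library came from a tumour.

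For adhesion, other splits of the same libraries gave results as large as the real ones, so these splits cannot exclude chance for any of the list counts, though a split can part the libraries titled number 6 unevenly, which the real groups do not, and its count may be too high for that reason. The 9 lists between weakly and strongly adherent tumours were matched or exceeded in 65 of 100 splits (highest other 16), the 4 lists between weakly adherent and unsorted in 93 of 100 (highest 18), and the 7 lists between strongly adherent and unsorted in 83 of 100 (highest 16). For genes the real count was 0 in each comparison, so all 100 of 100 splits were as large by construction, and the highest other splits gave 2, 0 and 74 genes, and 331 for any difference among the 3 groups. Splits with 74 and 331 genes where the real grouping has 0 point to a structure of the libraries other than adhesion, and which libraries drive those splits was not tested.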
